A study of uncultured bacterium with 30 samples.

How the data were processed

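Soil DNA from 30 grassland plots in Inner Mongolia was hybridized to GeoChip, a microarray of probes for microbial functional genes. Per the labels' protocols, topsoil was blown off the eroded plots with a fan in 2010 and 2011, and the collected soil was added to the deposition plots. Per the same protocols, 4 cores per plot were mixed into 1 composite sample in 2012, and the DNA was labelled with the dye Cy5. The cores were 10 cm deep and the topsoil is given as 1.5 to 3 cm, so the cores reached deeper than that layer. The 30 plots form 6 groups of 5: control, erosion and deposition without grazing, and grazing alone, erosion with grazing and deposition with grazing. The plots are separate pieces of ground with separate samples, so the spread between them holds both field and array variation. Groups and replicate numbers were taken from the labels.

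The values are linear spot intensities as the authors deposited them, in 2 tables, with a blank where a probe has no value. A blank was read as not detected. Image analysis, background correction, the detection threshold and the normalization are not given in the sources used here. The totals in the deposited tables show an array-wide scaling of intensity: the summed signal had a coefficient of variation of 5.02% over the 30 arrays, while the number of detected probes ranged from 14765 to 35728. The 2 tables list the same 58572 probes in the same order, and every probe has a value on at least 1 of the 30 arrays. This was taken to mean that the arrays were processed together, and groups from both tables were compared on that basis. It is a reading of the values that no label states. The files pair each probe with 1 of 778 gene names, 1 of 16 categories and a source organism. A gene name is called a gene family here. A family's name comes from the probe design and does not prove that the organism was present.

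Probes were tested on log2 intensity with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with undetected values missing and probes kept where at least 3 of 5 plots of each group had a value. Median intensities of the arrays differed by more than 5%, so the values were quantile normalized before the probe and gene list tests, as the design foresaw. The total signal was already level, so gene families, taxa, shares and distances used the values as deposited. For a family or taxon, the intensities of its detected probes were summed per plot, undetected probes counted as 0, and the log2 sums were tested with limma. Families needed at least 5 probes detected in some plot and a sum above 0 in every plot. Each set of 15 plots, ungrazed or grazed, was fitted alone with 1 mean per group and a shared spread. Adjusted p-values are Benjamini-Hochberg values per comparison with a threshold of 0.05. A share is the percentage of a plot's summed signal.

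The fixed gene lists numbered 26, of which 25 had at least 5 tested probes. They were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with an estimated correlation. Camera compares a list with all other probes of the array. A list score was computed for each plot as the mean log2 deviation of the list's probes from the mean of the set of plots, minus the same mean over all probes. Differences between groups in list scores, detected probes and shares were tested with two-sided exact permutation tests over the 252 splits of 5 against 5, whose smallest p is 0.00794. Community composition was compared by permutational multivariate analysis of variance on Bray-Curtis distances with vegan 2.7.1, with all 252 splits for pairs of groups and 9999 permutations for 3 groups. Differences of the erosion or deposition effect between grazed and ungrazed plots were tested in a limma model of all 30 plots with 6 group means. Whether replicate numbers pair the plots was judged for each comparison by the correlation of same-numbered plots' deviations from their group means over 3504 probes. All 5 pairs were above 0.1 in erosion against deposition (lowest 0.343) and in erosion with grazing against grazing alone (lowest 0.108). The numbers were taken to pair the plots there, by a cut in the same data and not by any label. This pairing is weak. Plots that correlated best with their own number counted 3 and 1 there, against 3 or 4 in the comparisons left unpaired. Over all comparisons 25 of 30 pairs were above 0.1. The fits have no block, as planned, and the paired tests of list scores, two-sided exact sign-flip tests, were chosen after the data were seen. The number of arrays limits the precision of every value.

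The named families followed a rule fixed before the data were examined. For erosion and deposition against control it takes up to 4 core families per list with the smallest p, drawn from 35 core gene names, and the 5 families of each direction with the smallest p outside them when none passes the threshold. It also takes up to 3 probes of each direction past the threshold, of which there were 0. For other comparisons it takes 3 families of each direction. Families named outside this rule are said to be so. Alternatives fixed in advance were the replicate number as a block, division of each array by its median, each plot left out in turn, only the compared groups in the fit, probes with a value in all 15 plots, undetected values as 0, family values as mean log2 signal, families with at least 1 probe, an estimated correlation, Jaccard and log2 distances, and a signal floor at the 25th percentile. Alternatives added after seeing the data were the other scaling (as deposited or quantile), an equal number of 14765 probes per array, the detected number as a covariate, fits without the plots numbered 5, the replicate block with only the 2 groups compared, and the other scalings and equal probe numbers for families compared between replicate numbers. The list for anammox was not tested, because too few of its probes passed the filter.

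The fits were tested on simulated data made from the residuals of the real plots. These were reassigned to the plots at random, so replicate numbers fell unevenly over the groups. In the real plots each number occurs once per group, so the shares recovered may differ from those of the real fits. For erosion against control, 84.9% of 200 probes and 96.8% of 60 families changed 4-fold were recovered on average over 20 repeats, against 6.80% and 76.2% at 2-fold, with 17289 probes and 483 families tested. For erosion with grazing against grazing alone, 78.5% of probes and 95.6% of families changed 4-fold were recovered, against 2.53% and 70.5% at 2-fold, with 16408 probes and 471 families tested.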

Results

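The soil DNA of 30 grassland plots was measured on GeoChip, a functional gene array on which each probe stands for a gene of a named source organism. Ungrazed plots were left as control, lost topsoil (erosion) or received it (deposition), and grazed plots had the same 3 treatments, with 5 plots in each of the 6 groups. Soil was sampled in 2012, the year after the last soil movement, with cores of 10 cm depth against 1.5 to 3 cm of topsoil. Arrays detected 14765 to 35728 of the 58572 probes, with a median of 22689. Summed signal was level, with a coefficient of variation of 5.02% over the 30 arrays, while the median intensity of detected probes ran from 26581 to 60246.

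Bacterial genes made up most of the signal in every group. In control plots, probes from bacteria held 88.8% ± 0.329 of the signal (SD, n = 5), those from fungi 6.45% ± 0.242, those from archaea 3.37% ± 0.345 and those from viruses 0.473% ± 0.0872. Erosion plots held 89.1% ± 0.478 bacterial and 3.10% ± 0.319 archaeal signal, and deposition plots 89.1% ± 0.385 and 3.17% ± 0.267. The 36 differences in share between groups, over 6 classes of source organism (eukaryotes and the fungi within them are separate classes, as are probes without a lineage) and 6 comparisons, all had an adjusted exact permutation p of 1. Carbon cycling genes took 35.9% ± 1.43 of the control signal, metal resistance genes 15.8% ± 0.902, nitrogen genes 10.4% ± 0.523 and stress genes 7.61% ± 0.358 (SD, n = 5 each). The families with the most signal in control plots were ppx, an exopolyphosphatase that breaks down stored polyphosphate, at 2.84% ± 0.286, and the general bacterial and archaeal chitinase family at 2.67% ± 0.291. Actinobacteria held 16.1% ± 1.96, Alphaproteobacteria 15.7% ± 0.899 and Gammaproteobacteria 14.7% ± 0.222 of the control signal.

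The first question of the design is whether soil movement altered how many functional genes were detected. Control plots had 21852 ± 6052 detected probes, erosion plots 26308 ± 6512 and deposition plots 24941 ± 4775 (SD, n = 5 each). The difference of erosion from control was 4456 probes (two-sided exact permutation p = 0.317), of deposition from control 3089 (p = 0.413) and of erosion from deposition 1367 (p = 0.698), which turned to -591.8 without erosion replicate 5. Among grazed plots, the counts were 26326 ± 6487 with grazing alone, 22596 ± 4800 with erosion and 22434 ± 7772 with deposition. Erosion with grazing differed from grazing alone by -3730 (exact p = 0.333), deposition with grazing by -3892 (exact p = 0.405), and the former from the latter by 161.8 (exact p = 0.960), with the other sign in 5 of the fits that left out 1 plot (lowest -1756). After adjustment over the 6 comparisons, p was 0.619 to 0.960. Within replicate numbers, erosion was higher than deposition in 4 of 5 pairs (exact sign-flip permutation p = 0.188) and erosion with grazing lower than grazing alone in 4 of 5 (exact p = 0.188). The 6 plots numbered 5 had 29985 to 35728 detected probes, a mean of 32940 ± 2410 (SD), and the 6 plots numbered 3 had 19926 ± 1325.

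**Figure D1:**
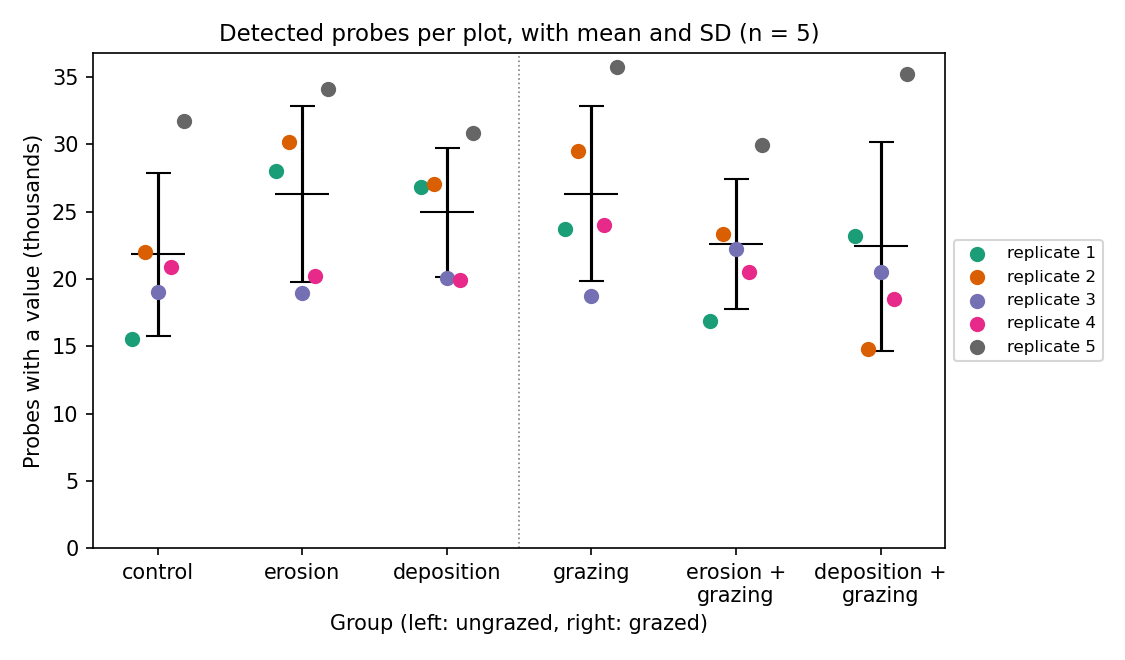
Number of detected probes, on an axis in units of 1000 probes, in each of the 30 plots, by group, coloured by replicate number, with the group mean and SD (n = 5). The 6 plots numbered 5 lie between 29985 and 35728, and the group means lie between 21852 and 26326.

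The composition of the functional gene community was compared next, as Bray-Curtis distances over all probes. Treatment accounted for 12.2% of the variation among the 15 ungrazed plots (permutation p = 0.548) and for 7.72% among the 15 grazed plots (permutation p = 0.980). Erosion against control accounted for 9.45% (exact permutation p = 0.452), deposition against control for 9.94% (exact p = 0.460) and erosion against deposition for 8.96% (exact p = 0.556; exact p = 0.0625 within replicate numbers, the smallest that 5 pairs allow). Without control replicate 5 the shares were 21.45% for erosion against control (exact permutation p = 0.111), 17.03% for deposition against control (exact p = 0.159) and 19.38% for the 3 groups (permutation p = 0.199). Leaving out this plot removes number 5 from control alone, so these shares mix treatment with replicate number. For grazed plots, the pairs accounted for 6.50% (exact p = 0.873), 6.61% (exact p = 0.825) and 4.59% (exact p = 0.976), and all 6 pairs had an adjusted p of 0.976. The mean distance between plots of 1 group was 0.387 in ungrazed and 0.426 in grazed plots, against 0.377 and 0.401 between plots of different groups. Plots of the same replicate number lay at a mean distance of 0.310 in ungrazed and 0.349 in grazed plots, against 0.391 and 0.418 for plots of other numbers. Replicate number, present once in every group, accounted for 51.0% of the variation in ungrazed and 47.5% in grazed plots. The permutations over all plots left this in the spread against which treatment was tested, so their p-values can be too high. Axis 1 of a principal coordinates analysis of all 30 plots held 41.1% of the variation and axis 2 held 12.7%. Axis 1 followed the number of detected probes, with Pearson's r = 0.949 and Spearman's rho = 0.958 (permutation p = 0.00001 for each, the smallest that 100000 permutations can give), and r = 0.944 without the 2 plots farthest from the median.

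**Figure D2:**
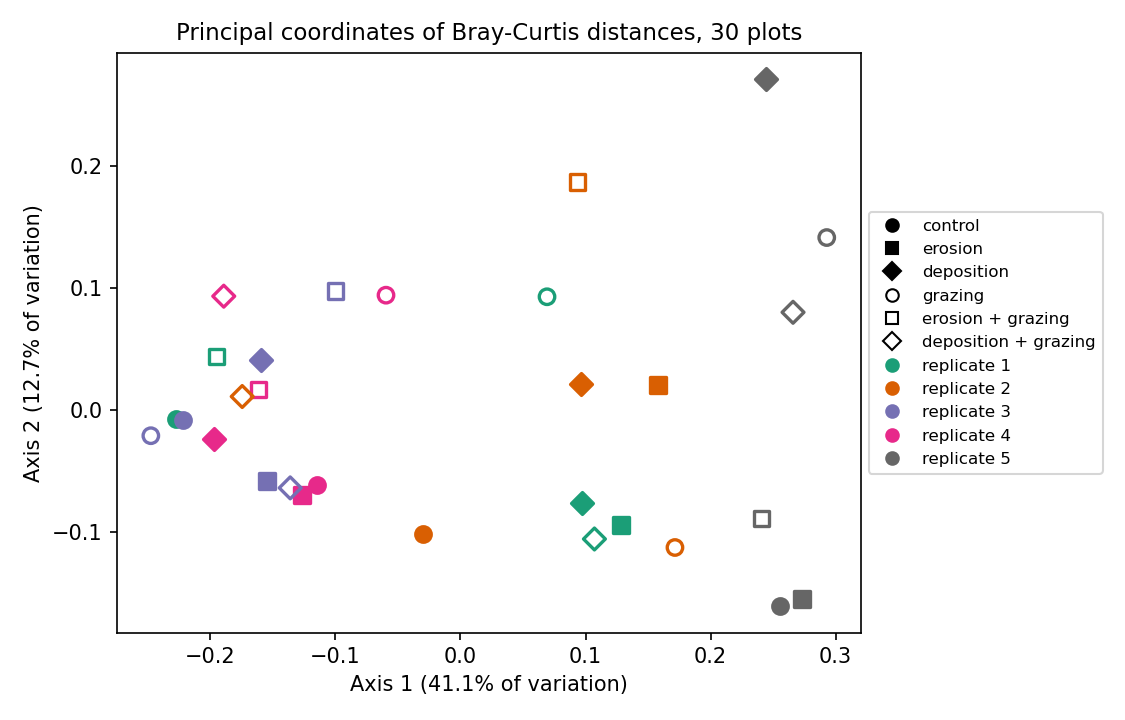
Principal coordinates of Bray-Curtis distances between the 30 plots. Axis 1 holds 41.1% and axis 2 holds 12.7% of the variation, each point is 1 plot, filled symbols are ungrazed and open symbols grazed, shape gives the soil treatment and colour the replicate number. Groups overlap. Plots numbered 5 lie at the high end of axis 1 and those numbered 3 and 4 on its negative side, while plots numbered 1 and 2 spread over much of the axis.

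Erosion against control in ungrazed plots addresses what removal of topsoil does to functional genes. Among carbon families, xylA, xylose isomerase of hemicellulose breakdown, had a log2 ratio of 0.22 ± 0.13 (SE, n = 5 plots a group), vanA, vanillate demethylase of lignin breakdown, 0.14 ± 0.09, and mnp, the fungal manganese peroxidase, 0.21 ± 0.16. The fungal cellulose families cellobiase_fungi and endoglucanase_fungi had 0.24 ± 0.18 and 0.15 ± 0.13. Methane genes pointed apart, with -0.35 ± 0.18 for pmoA, the methane monooxygenase of methane oxidizers, and 0.38 ± 0.26 for mcrA, the methyl-coenzyme M reductase of methanogens. No member of these groups passed the test. The nitrogenase families nifH and nifH_uncult_bact were at -0.19 ± 0.19 and -0.14 ± 0.22 as deposited, and both took a positive sign when arrays were divided by their median or quantile scaled.

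The nitrogen fixation list, made of those nifH families, was the only list of 25 that fell in erosion relative to control (camera in limma, 264 probes, adjusted p = 0.0429). Its call was lost with an estimated correlation (adjusted p = 0.973 with an estimated correlation). The list's median log2 ratio was 0.02, against 0.11 over all probes, so its median had the opposite sign to its test, which compares it with the other probes. Its plot scores differed by -0.119, with -0.092 ± 0.219 in erosion and 0.027 ± 0.267 in control plots (SD, n = 5, exact permutation p = 0.437). Without the plots numbered 5 the scores differed by -0.149 (exact p = 0.143). Erosion was lower in 5 of 5 same-numbered pairs (exact sign-flip p = 0.0625, the smallest possible, 0.709 adjusted over the lists). Of 25 lists 2 had 1 sign in all pairs, against 1.56 expected by chance. The call was also lost with values as deposited (adjusted p = 0.0923), with the number of probes per array made equal (0.298) and without erosion replicate 1 or 5, control replicate 1, 3 or 4 or any single deposition plot (0.0556 to 0.530), and the direction turned with the detected number as a covariate (0.875). The list's median minus that of all probes, -0.089 with all plots, was still -0.098 as deposited, -0.106 without control replicate 4 and -0.083 to -0.092 without a deposition plot, so these losses do not show a smaller difference, while it was -0.050 to -0.069 in the other fits that lost the call and kept the direction.

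Core families of denitrification had small ratios, 0.13 ± 0.13 for nosZ, nitrous oxide reductase, and 0.09 ± 0.09 for narG, nitrate reductase. In nitrogen turnover, gdh, glutamate dehydrogenase, had 0.16 ± 0.15, ureC, urease, 0.04 ± 0.08, napA, periplasmic nitrate reductase, 0.19 ± 0.13, nrfA, the ammonia-forming nitrite reductase, 0.02 ± 0.11, and nasA, assimilatory nitrate reductase, 0.02 ± 0.13. In nitrification, the archaeal ammonia monooxygenase family AmoA_Arch_non_Cren had 0.21 ± 0.27, and hao, hydroxylamine oxidoreductase, had -0.08 ± 0.14 with a positive sign under both other scalings. The same turn of sign held for rubisco, the carbon dioxide fixing enzyme (-0.09 ± 0.09), xylanase (-0.22 ± 0.16) and amyA_fungi, fungal alpha-amylase (-0.21 ± 0.17). Bacterial amylase amyA_Actinobacteria had 0.17 ± 0.19. The chitin family acetylglucosaminidase had 0.09 ± 0.11 and its fungal counterpart acetylglucosaminidase_fungi -0.43 ± 0.61. Phosphorus and sulphur families were ppk, polyphosphate kinase, at 0.10 ± 0.11, ppx_fungi at -0.40 ± 0.58 and dsrA, dissimilatory sulfite reductase, at 0.01 ± 0.09.

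Of the 57 core families tested, 0 passed limma's threshold over all families and 0 did when adjusted over the list alone (smallest adjusted p = 0.996). As deposited, 34 were higher and 23 lower in erosion, and 52 were higher with arrays divided by their median. That scaling moved the median family from 0.02 to 0.26 on the log2 scale. Relative to the median family 24 of the 57 were higher under both, which is fixed in advance, as the division moves every family of an array alike. The 95% confidence interval lay within 2-fold either way for 52 of the 57, and for 400 of all 483 families. Over all families limma called 0 of 483, with 10 at an unadjusted p under 0.05, and over probes 0 of 17289, with 231 at an unadjusted p under 0.05. These are 2.07% of families and 1.34% of probes, fewer than chance gives on average at that threshold. Among families outside the core, the smallest p values belonged to LMO at 0.96 ± 0.37, lactase_fungi at 0.52 ± 0.22, metalloprotease_fungi at 0.49 ± 0.21, srt at 0.51 ± 0.22 and tfdA, a dioxygenase of phenoxyacetate herbicide breakdown, at 0.50 ± 0.21 on the higher side. On the lower side they were related_thiosulfate_gene at -1.52 ± 0.52, mannanase_fungi at -0.52 ± 0.19, ZitB, a zinc exporter, at -0.33 ± 0.14, chnC at -0.47 ± 0.23 and per_bac at -0.25 ± 0.12. All 10 had an adjusted p of 0.994. LMO held 0.0162% ± 0.00233 of the signal in erosion and 0.00961% ± 0.00512 in control plots (SD, n = 5).

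Among taxa, 0 of 20 passed limma's threshold and 1 had an unadjusted p under 0.05. It was Thaumarchaeota, the phylum of soil ammonia-oxidizing archaea, at 0.43 ± 0.16 from only 9 probes (adjusted p = 0.300). It passed with the plots numbered 5 left out (0.485, adjusted p = 0.0333) and without deposition replicate 5 (adjusted p = 0.0393). Actinobacteria held 17.4% ± 1.84 of the erosion and 16.1% ± 1.96 of the control signal (SD, n = 5). With undetected probes set to 0, 2 probes fell in erosion: fccAB of Thiothrix nivea, a flavocytochrome gene of sulfide oxidation, and ccmL of Planctomyces brasiliensis (adjusted p = 0.00460 for each). Both were detected in 0 erosion and 5 control plots, and both were named after their values were seen. All 5 erosion values of each probe were thus 1 constant, without spread, so limma's p can be too small. It lies below 0.00794, the smallest p that the exact permutation of 5 against 5 allows.

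**Figure D3:**
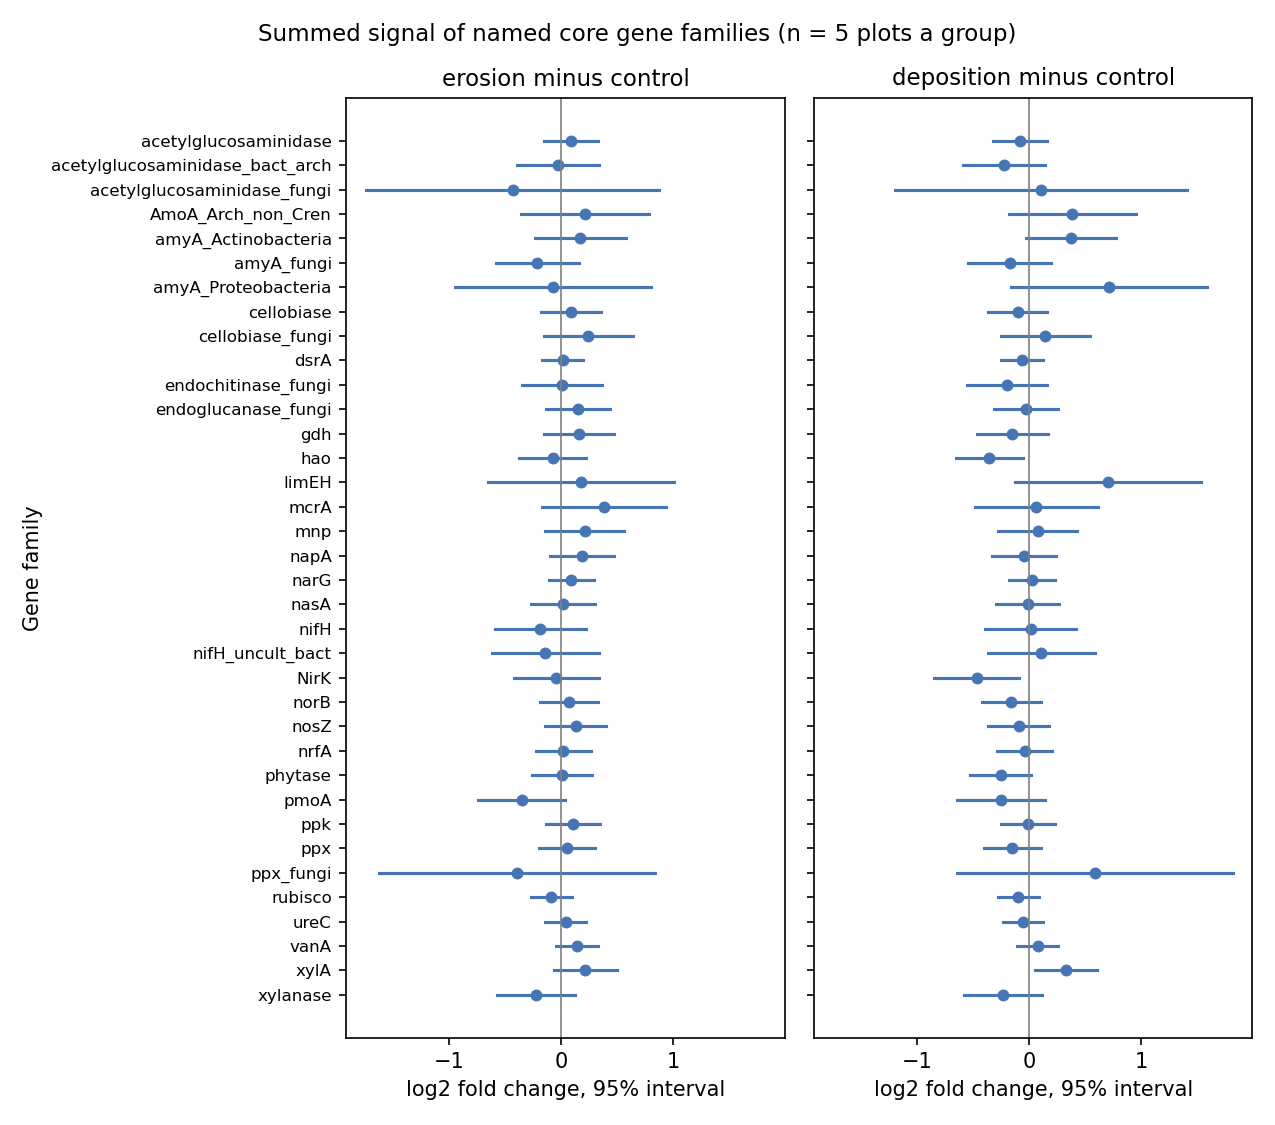
Log2 fold change of summed signal (points) with the 95% confidence interval (lines) for the named core gene families in ungrazed plots, erosion minus control on the left and deposition minus control on the right (n = 5 plots a group, values as deposited). No family passed limma's threshold. With arrays divided by their median all points shift up together, taking the median family from 0.02 to 0.26 in erosion and from -0.01 to 0.20 in deposition, so points less than that shift below 0 turn positive.

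Deposition against control addresses what added topsoil does. Starch genes stood apart from the other probes: the starch list of amylases and debranching enzymes rose in deposition plots (camera in limma, 1504 probes, adjusted p = 1.42e-08, adjusted p = 0.979 with an estimated correlation). Its median log2 ratio was 0.15, against -0.01 over all probes. The amylase family amyA_Proteobacteria had a log2 ratio of 0.71 ± 0.41 (SE, n = 5 plots a group) and amyA_Actinobacteria 0.37 ± 0.19, which is 2.52% ± 0.768 of the signal in deposition and 1.92% ± 0.408 in control plots (SD). None of the 13 starch families passed the test, with 8 higher and 5 lower. The plot scores of the list were 0.140 ± 0.206 in deposition and -0.034 ± 0.238 in control plots (SD, n = 5), a difference of 0.174 (exact permutation p = 0.278). Replicate 5 had scores of 0.453 in deposition and -0.413 in control, and without the plots numbered 5 the difference was 0.001, with the list at an adjusted p of 0.922. The call was lost without control replicate 5 alone (adjusted p = 0.635).

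Among the named core families NirK, hao and phytase had the lowest ratios in deposition, while their lists were mixed: 5 of 7 denitrification, 1 of 3 nitrification and 3 of 5 phosphorus families were lower, and none of the 3 lists passed in camera (adjusted p = 0.520, 0.520 and 0.442). NirK, a nitrite reductase family that the files spell apart from nirK, had -0.47 ± 0.18, hao had -0.36 ± 0.14, and phytase, which frees phosphate from plant phytate, had -0.26 ± 0.13. The denitrification family norB, nitric oxide reductase, had -0.16 ± 0.12 and ppx -0.15 ± 0.12, both of positive sign under the other scalings. Higher ratios were seen for xylA (0.33 ± 0.13), AmoA_Arch_non_Cren (0.39 ± 0.27) and limEH, limonene epoxide hydrolase (0.70 ± 0.39). Lower ratios that kept their sign but lost most of their size under the other scalings were -0.22 ± 0.17 for acetylglucosaminidase_bact_arch, -0.23 ± 0.16 for xylanase and -0.25 ± 0.18 for pmoA. With arrays divided by their median they were -0.016, -0.025 and -0.045, and with quantile scaling -0.006, -0.028 and -0.030. Ratios within 0.20 of 0 were measured for cellobiase (-0.10 ± 0.12), cellobiase_fungi (0.15 ± 0.18), endochitinase_fungi (-0.19 ± 0.17), rubisco (-0.10 ± 0.09) and vanA (0.07 ± 0.09), and also for mcrA (0.06 ± 0.26), nasA (-0.01 ± 0.13), nifH (0.01 ± 0.19) and nifH_uncult_bact (0.11 ± 0.22). In this range were also gdh (-0.15 ± 0.15), ureC (-0.05 ± 0.08), nrfA (-0.04 ± 0.11), napA (-0.05 ± 0.13) and dsrA (-0.06 ± 0.09). Of these, cellobiase, endochitinase_fungi, rubisco, nasA, gdh, ureC, nrfA, napA and dsrA turned positive under both other scalings.

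Of the 57 core families, 0 passed limma's threshold over all families and 0 when adjusted over the list alone (smallest adjusted p = 0.472), with 3 at an unadjusted p under 0.05. As deposited 24 were higher and 33 lower, and 49 were higher with arrays divided by their median, which moved the median family from -0.01 to 0.20. Relative to that median, 24 were higher, the same under both by construction. Limma called 0 of 483 families, with 19 at an unadjusted p under 0.05, and 0 of 17289 probes, with 411. Those are 3.93% of families and 2.38% of probes, again fewer than chance gives on average. The 95% confidence interval lay within 2-fold for 49 of the core and 397 of all families.

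Outside the core, LMO had the highest ratio of the deposition comparison among the families named, at 1.36 ± 0.37, with 0.0231% ± 0.00914 of the signal against 0.00961% ± 0.00512 in control plots (SD, n = 5). Its adjusted p was 0.652 over all families and 0.0486 when adjusted over the list alone, that for lignin and aromatic compounds. LMO was named for its small p, so the adjustment over its own list is no separate support. In that list 14 of 18 families were higher, and its plot scores differed by 0.05 (exact permutation p = 0.421). The other families named on the higher side were inv at 0.95 ± 0.36, bphD of biphenyl breakdown at 0.63 ± 0.25, groEL, a chaperonin, at 0.55 ± 0.25 and xylF at 0.77 ± 0.37. On the lower side, hdnO of nicotine breakdown had -0.63 ± 0.17 (adjusted p = 0.652), phoB, the phosphate starvation regulator, -0.31 ± 0.12, soxA of thiosulfate oxidation -0.38 ± 0.14, CysI, a sulfite reductase subunit, -0.36 ± 0.14 and atzC of atrazine breakdown -0.41 ± 0.16. Of 20 taxa, 0 passed limma's threshold and 1 had an unadjusted p under 0.05. This was again Thaumarchaeota, at 0.47 ± 0.16 (adjusted p = 0.184), against the same control plots as for erosion. It passed with the replicate block and only the 2 groups compared, a fit chosen after the data were seen (adjusted p = 0.0245).

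**Figure D4:**
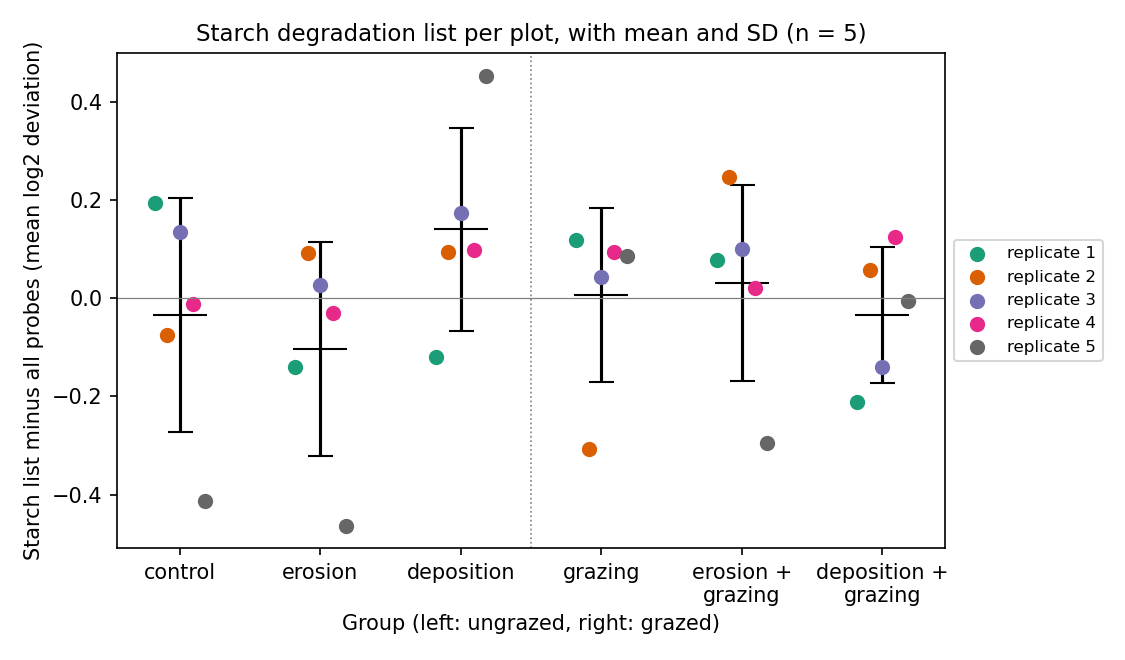
Score of the starch list in each of the 30 plots, the mean log2 deviation of its probes minus that of all probes within the ungrazed or the grazed set, coloured by replicate number, with the group mean and SD (n = 5). In the ungrazed set, replicate 5 lies at -0.413 in control, -0.463 in erosion and 0.453 in deposition.

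Erosion against deposition sets plots that lost soil against plots that received it. Starch genes again stood apart, and the list fell in erosion relative to deposition (1504 probes, median log2 ratio -0.15 against 0.11 over all probes, adjusted p = 3.26e-16, adjusted p = 0.497 with an estimated correlation). The nitrogen fixation list fell too (264 probes, median -0.07, adjusted p = 4.67e-05, adjusted p = 0.939 with an estimated correlation). The denitrification list rose (733 probes, median 0.20, adjusted p = 0.0236) and so did the phosphorus list (669 probes, median 0.20, adjusted p = 0.0444), each with an adjusted p = 0.939 with an estimated correlation. Of the starch families 9 of 13 were lower, of the denitrification families 6 of 7 were higher, and 0 families of these lists passed limma's threshold or did so when adjusted over the list alone. Amylase families named after their values were seen were amyA_Proteobacteria at -0.79 ± 0.41 and amyA_other at -0.68 ± 0.40 (SE, n = 5 plots a group). In plot scores, starch differed by -0.243 (exact permutation p = 0.103; -0.075 without the plots numbered 5), nitrogen fixation by -0.162 (exact p = 0.206; -0.078 without the plots numbered 5), denitrification by 0.081 (exact p = 0.111) and phosphorus by 0.085 (exact p = 0.103). Within replicate numbers, starch and nitrogen fixation were lower and denitrification higher in erosion in 5 of 5 pairs (exact sign-flip permutation p = 0.0625 for each, the smallest that 5 pairs allow), and phosphorus was higher in 4 of 5 (exact p = 0.125). The starch differences ran from -0.001 to -0.916. Of 25 lists 3 had 1 sign in all pairs, against 1.56 expected by chance, and the smallest p adjusted over the lists was 0.427. With the replicate block the nitrogen mineralisation list also passed as higher in erosion (adjusted p = 0.0488, against 0.111 without the block and adjusted p = 0.939 with an estimated correlation and no block). The denitrification call was lost without erosion replicate 5, deposition replicate 3 or deposition replicate 4 (adjusted p = 0.113 to 0.192), and the phosphorus call without those and without erosion replicate 1, control replicate 1 or 3 or deposition replicate 1 (adjusted p = 0.0503 to 0.227). For phosphorus the list's median minus that of all probes, 0.088 with all plots, was still 0.087, 0.090 and 0.106 without control replicate 1, control replicate 3 and deposition replicate 1.

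Limma called 0 of 483 families between erosion and deposition, with 10 at an unadjusted p under 0.05, and 0 of 17289 probes, with 292. Here too the shares, 2.07% of families and 1.69% of probes, were below what chance gives on average. Of 57 core families, 0 passed over all families or when adjusted over the list alone (smallest adjusted p = 0.598). The families with the smallest p were trzE at 0.94 ± 0.35, atzD, a cyanuric acid hydrolase, at 0.38 ± 0.15 and sqr, sulfide quinone reductase, at 0.35 ± 0.14 on the higher side. On the lower side they were related_thiosulfate_gene at -1.20 ± 0.52, dmdA, which demethylates the sulfur compound dimethylsulfoniopropionate, at -0.31 ± 0.14 and CysJ, a sulfite reductase flavoprotein, at -0.49 ± 0.26. All 6 had an adjusted p of 0.989. Limma called 0 of 20 taxa, with 0 at an unadjusted p under 0.05. With undetected probes set to 0, the same fccAB and ccmL probes of Thiothrix nivea and Planctomyces brasiliensis fell in erosion (adjusted p = 0.00263 for each), both detected in 0 erosion and 5 deposition plots. The erosion values are the same constants as against control, so this is no separate support.

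In grazed plots, the same soil treatments were set against grazing alone. With erosion, the families of smallest p were NRPS, nonribosomal peptide synthetases, at 0.58 ± 0.26, arcB, an oxygen-responsive sensor kinase, at 0.71 ± 0.33 and soxV at 0.49 ± 0.31 on the higher side (SE, n = 5 plots a group). On the lower side they were inv at -0.48 ± 0.15, lactase_fungi at -0.59 ± 0.20 and sulfate_transporter at -0.42 ± 0.17. With deposition they were arcB at 1.01 ± 0.33, aclB, the citrate lyase of the reductive citric acid cycle, at 0.47 ± 0.17 and soxV at 0.70 ± 0.31, and on the lower side lactase_fungi at -0.58 ± 0.20, katA, a catalase, at -0.94 ± 0.33 and SilA, a silver efflux pump, at -0.78 ± 0.30. None of them passed, with adjusted p of 0.996 for erosion and 0.984 for deposition. For erosion with grazing against deposition with grazing they were pchCF at 1.32 ± 0.55, mdlD at 0.65 ± 0.31 and todC, toluene dioxygenase, at 0.45 ± 0.23, and ahpF, an alkyl hydroperoxide reductase, at -0.62 ± 0.23, aclB at -0.44 ± 0.17 and CysI at -0.31 ± 0.16 (adjusted p = 0.997).

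For grazed plots limma called 0 of 471 families in each of the 3 comparisons, with 11, 13 and 3 at an unadjusted p under 0.05 for erosion, deposition and their difference. It called 0 of 16408 probes, with 188, 135 and 61, and 0 of 20 taxa, with 0 in each. The counts under 0.05 were 2.34%, 2.76% and 0.637% of families and 1.15%, 0.823% and 0.372% of probes. Chance gives more on average. Of 56 core families 0 passed in any of the 3, over all families or adjusted over the list alone. As deposited, 28 core families were higher under erosion and 28 under deposition, and 5 and 3 were higher with arrays divided by their median, which moved the median family from -0.07 to -0.22 and from -0.07 to -0.29. Relative to the median family, 39 and 41 were higher, the same under both scalings by construction. No list passed at the preset correlation, with 0, 4 and 3 lists at an unadjusted p under 0.05. The lists closest to the threshold were nitrogen assimilation and nitrogen mineralisation in deposition with grazing against grazing alone, both with an adjusted p of 0.0508 in camera and 0.991 with an estimated correlation. With arrays divided by their median, 4 lists passed in that comparison, and with the replicate block and only the 2 groups compared the nitrogen assimilation list passed (adjusted p = 0.0465).

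The factorial layout also asks whether grazing altered the effect of soil movement. For erosion, lactase_fungi had the smallest p, with a log2 difference between the grazed and the ungrazed effect of -1.11 ± 0.30 (SE, limma adjusted p = 0.455). For deposition, aclB had a difference of 0.73 ± 0.23, CysI 0.57 ± 0.20 and arcB 1.44 ± 0.53, and on the other side LMO had -1.73 ± 0.56, inv -1.22 ± 0.40 and bphD -0.98 ± 0.34 (adjusted p = 0.669). Each difference includes the ungrazed deposition effect given above, against the same control plots, and is not independent of it. Limma called 0 of 472 families for erosion and 0 for deposition, with 19 and 28 at an unadjusted p under 0.05, and 0 of 14446 probes for each, with 318 and 359. As shares, 4.03% and 5.93% of families and 2.2% and 2.49% of probes were near or under what chance gives on average. For the number of detected probes, the erosion effect differed by -8187 between grazed and ungrazed plots (exact permutation p = 0.134) and the deposition effect by -6981 (exact permutation p = 0.223), over 63504 label assignments.

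Grazing alone against control, taken across both tables, gave 0 of 472 families with 18 at an unadjusted p under 0.05, and 0 of 14446 probes with 422. That is 3.81% of families and 2.92% of probes, fewer than chance gives on average. The families with the smallest p were bphD at 0.69 ± 0.24, LMO at 1.12 ± 0.40 and dmdA at 0.39 ± 0.14 on the higher side. On the lower side they were hdrB, a heterodisulfide reductase subunit of methanogens, at -1.01 ± 0.33, CysI at -0.42 ± 0.14 and arcB at -1.02 ± 0.38 (SE, limma adjusted p = 0.827 for all 6). LMO, bphD and CysI were also named in deposition, and LMO in erosion, against the same control plots, so these comparisons are not independent.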

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

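The tests of explanations and the counts over other splits of the plots in this part were chosen after the results were seen. Of 162 groups of 5 plots examined for a plot far from the others, over 27 measures, 5 held one, and chance gives about 5% of groups. Control replicate 5 had 3.19% of its signal in the category of fungal functions, against 2.73% to 2.84% in the other control plots. Replicate 2 of erosion with grazing had 1.97% in the category that the files name soil_benifit, against 1.74% to 1.80%. Replicate 2 of grazing alone had a starch list score of -0.307, against 0.043 to 0.119. Replicate 5 of erosion with grazing had a denitrification score of 0.149, against -0.107 to -0.057, and a nitrogen fixation score of -0.336, against 0.049 to 0.153.

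Functional gene composition differed between replicate numbers across treatments, mainly between number 5 (mean Bray-Curtis distance 0.317 among its plots) and numbers 3 and 4 (0.524 and 0.497 from number 5), while plots numbered 1 lay no closer to each other (0.374) than to those numbered 2 (0.350). Replicate number accounted for 41.8% of the variation in composition among the 30 plots (permutation p = 0.0001, the smallest that the permutations can give) and the 6 groups for 12% (permutation p = 0.933), and 122 of 472 families differed between replicate numbers in limma, against at most 1 in the other splits drawn (1 of 100 with the real one), so chance can be excluded. Replicate number accounted for 43.0% when every array was reduced to its 14765 strongest probes. That reduction kept the deposited intensities, and the median family was then at -0.311 in plots numbered 5 and 0.229 in those numbered 3. A difference in intensity between these plots thus stayed in. The reduction therefore cannot decide whether the number of detected probes accounts for the difference in composition. A run of arrays or a position in the field may account for it, and these cannot be told apart, because the labels name neither and the sample numbers run in step with the replicate numbers: in 0 plots does the run of 6 sample numbers differ from the replicate number. No biological explanation was tested.

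The starch list stood apart between deposition and control (adjusted p = 0.979 with an estimated correlation) and between erosion and deposition (adjusted p = 0.497 with an estimated correlation). For deposition against control, the plot scores gave an exact permutation p of 0.278, so the spread between plots may account for it. For erosion against deposition the spread between plots stays open: all 5 pairs of same-numbered plots had the same sign, with an exact sign-flip permutation p of 0.0625, the smallest that 5 pairs allow. Both rested in large part on the plots numbered 5, without which the differences in score were 0.001 and -0.075. Without those plots erosion differed from control by -0.074 and from deposition by -0.075 (exact permutation p = 0.371 for each). These values lie within the spread between plots, so they cannot place what remains of the second difference with topsoil removal or with added topsoil. A biological effect of either stays open and untested.

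Counts of lists past the threshold were set against 100 splits of the plots per comparison. Chance could not be excluded for the 1 list of erosion against control (64 splits gave as many, highest other 6), the 1 list of deposition against control (65 splits, highest other 7) or the 4 lists of erosion against deposition (5 splits, highest other 5). Of the 16 splits that part all 5 pairs of same-numbered plots, as the treatments do, 2 gave 4 lists or more with the real one counted (highest other 4), and 16 are too few for a share under 0.05; in the other splits some same-numbered plots fall on one side. For erosion with grazing against grazing alone the highest of those splits were 1 probe, 1 family, 0 taxa and 7 lists. For the counts of 0, which all 100 splits reach, other splits called up to 4769 probes, 97 families and 11 taxa for erosion against control, up to 2258 probes, 16 families and 11 taxa for deposition against control, and up to 2015 probes, 4 families and 6 taxa for erosion against deposition. For grazed plots the highest were 2508 probes, 1 family, 9 taxa and 7 lists for erosion against grazing alone, 1 probe, 4 families, 1 taxon and 7 lists for deposition against grazing alone, and 1 probe, 2 families, 1 taxon and 6 lists for erosion against deposition. For the difference of effects with grazing they were 2136 probes and 12 families for erosion and 116 probes and 6 families for deposition, and for grazing against control 1 family. A split that calls 4769 probes where the treatments call 0 points to a structure of the plots, but such splits were few: of the splits other than the real one, 4, 1 and 5 called any probe in the 3 ungrazed comparisons, about as many as the threshold gives by chance.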

How the results depend on the processing

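The scaling as deposited or by quantiles, the equal number of probes per array, the detected number as a covariate, the fits without the plots numbered 5 and the block with only the 2 groups compared were chosen after the data were seen; the other alternatives were planned. The counts of 0 for families, the interaction and grazing alone held under every alternative run, and those for probes and taxa did with the exceptions given here. With undetected values as 0, 2 probes passed for erosion against control and the same 2 for erosion against deposition, each with 1 constant value in all 5 erosion plots. Counts of lists moved most. With an estimated correlation, the 1, 1 and 4 lists of the ungrazed comparisons became 0, 0 and 0. For erosion against control the count was 0 as deposited, 0 with equal probe numbers, 0 with the covariate and 5 without the plots numbered 5, and for deposition against control 6 with the covariate and 0 without the plots numbered 5. For deposition with grazing against grazing alone it was 4 with arrays divided by their median, 3 as deposited, 1 with equal probe numbers and 6 with the covariate. For erosion with grazing against deposition with grazing it was 2 as deposited, 3 with equal probe numbers, 2 with the covariate and 6 without the plots numbered 5, and for erosion with grazing against grazing alone 3 without them. Without the plots numbered 5, 1 taxon passed for erosion against control. The direction reversed for the nitrogen fixation list of erosion against control with the covariate (0.032) and for the starch list of deposition against control without the plots numbered 5 (-0.011). Apart from the estimated correlation, which widens the null, and the fits with fewer plots, the cause was not tested.

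With each plot left out in turn, the count of lists ran from 0 to 4 for erosion against control (4 without control replicate 5, 2 without erosion replicate 2), from 0 to 2 for deposition against control (0 without control replicate 5, 2 without control replicate 3 or deposition replicate 1) and from 2 to 5 for erosion against deposition. In grazed plots it ran from 0 to 2 for erosion against grazing alone (2 without replicate 5 of erosion with grazing), from 0 to 5 for deposition against grazing alone (5 without replicate 4 of deposition with grazing) and from 0 to 4 for erosion against deposition (4 without replicate 5 of erosion with grazing). The count of taxa for erosion against control ran from 0 to 1. The difference in detected probes between erosion and deposition ran from -591.8 (without erosion replicate 5) to 3197, and between erosion with grazing and deposition with grazing from -1756 (without replicate 2 of deposition with grazing) to 3357. The latter also turned negative without replicate 2 or 5 of erosion with grazing and without replicate 3 or 4 of deposition with grazing. No single plot turned a difference between a soil treatment and its control. Composition did not pass the threshold with any plot left out. The share for erosion against control was 17.72% without all plots numbered 5 (exact permutation p = 0.229). Each fit with 1 plot left out takes a replicate number from 1 group only, so its change can reflect that imbalance.

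Of 926 values of the named families under alternatives, 79 had the other sign and 0 passed the threshold. Between the 3 scalings, 17 of the 98 named values changed sign. In the 4 comparisons whose pairs did not all reach 0.1 (3 or 4 of 5 did), the replicate number served as an alternative block. Pairs are given there only for the list scores of erosion against control. With the replicate block, the lists of erosion against deposition numbered 5, and the block changed no other call. With the block and only the 2 groups compared, the lists of erosion against deposition numbered 5 again; the fifth, in both fits, was nitrogen mineralisation (without the block, adjusted p = 0.939 with an estimated correlation). Nitrogen assimilation passed for deposition with grazing against grazing alone (without the block, adjusted p = 0.991 with an estimated correlation), and the taxon Thaumarchaeota for deposition against control (0.468, adjusted p = 0.0245). Of families compared between replicate numbers, 122 of 472 differed as deposited, 347 with arrays divided by their median, 345 with quantile scaling and 237 of 401 with equal probe numbers, all chosen after the data were seen. The median family of plots numbered 5 was in turn at 0.002, 0.522, 0.528 and -0.311. The larger counts thus came with a shift of families in general, upward or downward by setting. In 19 of 60 checks a plot correlated best with its own number. At 2-fold, 6.80% of simulated changes were recovered among 17289 probes for erosion against control, against 76.2% among its 483 families.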

Other observations

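The families in this part were chosen after their values were seen, and their values are those of the signal as deposited. Several families that differed between replicate numbers belong to organisms or functions that the soil treatments do not name. The arsenic_resistance_gene family was 1.30 above the mean of all plots on the log2 scale in the 6 plots numbered 5 and -0.91 in those numbered 4 (limma adjusted p = 0.000115), and glnA_fungi, fungal glutamine synthetase, was at 0.77 and -0.53. The family bglH was at -1.39 in plots numbered 5 and 0.45 in plots numbered 4 (adjusted p = 1.64e-05), and acetylglucosaminidase_fungi, which cleaves chitin fragments, was at -1.37 and 0.63. With quantile scaling, the 4 families were at 1.809 and -1.091, 1.288 and -0.716, -0.869 and 0.244, and -0.859 and 0.429, and all 4 passed (adjusted p of 0.000443 or less).

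Genes of Tombusvirus, a genus of plant viruses with an RNA genome, gave signal although the array was hybridized with genomic DNA. The family replicase_Tombusvirus was at -0.80 in plots numbered 5 and at 0.54 in plots numbered 3 (limma adjusted p = 3.17e-05), and coat_Tombusvirus at -0.445 and 0.462 (adjusted p = 0.000144). With arrays divided by their median, coat_Tombusvirus was at 0.075 and 0.212 and did not pass (limma adjusted p = 0.0884), while replicase_Tombusvirus did (adjusted p = 0.0217). The family RNA_dependent__RNA_polymerase, whose name gives no virus, was at -0.87 and 0.55 as deposited. The plots numbered 5 had more detected probes of lower median intensity. With quantile scaling replicase_Tombusvirus was at -0.259 and 0.183 and did not pass (limma adjusted p = 0.138). RNA_dependent__RNA_polymerase was at -0.338 and 0.254 (adjusted p = 0.00316). That scaling also moved the median family, from 0.002 to 0.528 in plots numbered 5 and from 0.067 to -0.228 in those numbered 3. The smaller values thus went with a shift of families in general. Under that scaling replicase_Tombusvirus and RNA_dependent__RNA_polymerase stayed below the median family in plots numbered 5 and above it in plots numbered 3. The plots numbered 3 and 4 were the closest pair of replicate numbers in composition, with a mean Bray-Curtis distance of 0.282 between them, against 0.524 between numbers 3 and 5 and 0.497 between numbers 4 and 5.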
